A study of Mus musculus with 6 samples.

How the data were processed

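Liver RNA of C57BL/6 mice was measured on 6 Affymetrix 3' expression arrays, 1 array per liver sample. Per the labels' protocols, the mice received an intravenous AAV8 vector, an adeno-associated virus serotype that transduces the mouse liver, carrying either Nfkbiz or, as the control, luciferase. After 4 weeks they were placed for another 4 weeks on CDAHFD, a choline-deficient, amino acid-defined, high-fat diet used to model nonalcoholic fatty liver disease. The animals were perfused with buffered saline before the liver was taken, and biotin-labelled cRNA was made from 100 ng of total RNA. The sample titles give the groups, AAV8-luciferase and AAV8-Nfkbiz, with 3 arrays each and replicate numbers 1 to 3. The time of day at sampling, the feeding state and the scan dates are not given in the sources used here.

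The deposited values are MAS5 signal intensities on a linear scale, and MAS5 was the authors' method per the submitters' processing notes, with the version not given in the sources used here. From the values themselves, the mean of the middle 96% of intensities lay between 495.1 and 496.3 on all 6 arrays, so each array had been scaled to one target. Median intensities were between 78.2 and 95.2, and the highest intensity on an array was between 52443 and 67210. The table held 45037 probe sets, and the control probe sets of the platform are not analysed here, so the planned comparison of spike-in and 3'/5' controls was not made. For arrays, the number of samples limits the precision.

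Probe sets were named through the GEO platform annotation, which listed 35877 of them. Of these, 34945 had 1 gene symbol and 932 had several, and 9160 probe sets were not listed and stay unnamed here. Through the Entrez identifiers, 34741 of the probe sets with 1 gene were found in a RefSeq gene table of the assembly GRCm38.p6, and this update changed 0 symbols. No coordinates were used. Each of the 18193 genes was represented by its probe set with the highest mean log2 intensity over all 6 arrays. Genes whose representative fell among the lowest 40% of probe sets by mean, which corresponds to an intensity of 47.4, were left out, and 13312 genes were tested.

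Intensities were log2-transformed with no pseudocount and no further normalization between arrays. Differences are AAV8-Nfkbiz minus AAV8-luciferase on the log2 scale, fitted with limma 3.58.1 (lmFit, and eBayes with an intensity trend) in R 4.3.3. The tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Errors of differences of genes and probe sets are limma's moderated standard errors (SE). Errors of intensities are standard deviations (SD) over the 3 arrays of a group. Errors of differences in marker means, used in the closing section, are standard errors from the variances of both groups, without moderation. The labels do not say more than that the arrays are separate samples, so the p-values measure the spread between these samples. Where a single value was compared between groups, the exact two-sided permutation p cannot fall below 0.1 with 3 arrays against 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

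Before the data were examined, 31 gene lists were fixed. The 7 primary ones covered de novo lipogenesis, triglyceride synthesis and lipid droplets, fatty acid oxidation, the acute phase response, reported IκBζ targets, NF-κB feedback and target genes, and fibrosis. The others covered cell type markers, further metabolic pathways, stress responses, the cell cycle, the circadian clock and sex-biased liver genes. Lists with at least 5 measured members, 29 in all, were tested with limma's camera, a competitive test that asks whether the members' statistics are shifted against those of other genes, with a preset correlation between members of 0.01. The same test with an estimated correlation and limma's fry, which asks whether the members move on balance one way without comparing them with other genes, were run beside it. Members were counted after adjustment over all genes and after adjustment over the list alone.

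The genes named were set by a rule fixed at the same time, as were the alternatives. It took Nfkbiz, up to 12 genes per direction with the largest difference among those past the threshold with no overlap between the groups, up to 4 members of each list with the smallest unadjusted p, and 16 genes of lipid metabolism, inflammation and fibrosis in any case. Open places in a direction went to the genes with the smallest unadjusted p, no overlap and a log2 difference of at least 1. Gene models without a given name were passed over. Other genes named in the text, among them further list members that passed after adjustment over the list alone, were chosen after their values were seen.

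The procedure was tested on 20 simulated data sets of 13312 genes with the spread of these arrays and 200 changed genes each. It recovered 44.6% of the genes changed by a log2 difference of 1 and 78.1% of those changed by 2, and 3.88% of its calls were false. A list shifted by a log2 difference of 0.5 was found in 20 of 20 runs, and 1 list without a shift was called over the 20 runs of 29 lists, in simulations whose genes were independent of each other. Alternatives covered quantile, median and loess normalization, no filter and a stricter filter at 60%, an intensity floor and a pseudocount at the 20th percentile, other variance priors and array weights, other choices of probe sets, the probe set as the unit of the test, other thresholds, a per-gene Welch test, the replicate number as a block, camera on ranks, and leaving out each array in turn.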

Results

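Gene expression was measured in liver samples of mice given an AAV8 vector carrying Nfkbiz, the gene of the atypical nuclear IκB protein IκBζ, or a luciferase control vector, after 4 weeks of CDAHFD feeding. The single comparison of the design, 3 Nfkbiz arrays against 3 luciferase arrays, asked which liver transcripts differ between the 2 vectors on this diet. IκBζ protein and steatosis were not measured here. Values are MAS5 intensities scaled by the authors, and differences are on the log2 scale. Sampling times and feeding states are not given in the sources used here. Differences between the groups therefore cannot be assigned to the vector alone. Pairs of arrays within a group correlated at r = 0.962 to 0.971 across genes (6 pairs) and pairs from different groups at 0.959 to 0.968 (9 pairs), where genes are not independent replicates. The first principal component held 26.6% of the variance, and components 2 to 5 held between 13.5% and 22.9% each. It separated the groups, with luciferase arrays at -31.2, -17.2 and -10.1 and Nfkbiz arrays at 16.9, 37.8 and 3.75. The third luciferase array stood apart on the second component, at -45.1, where the other arrays lay between 3.11 and 21.1.

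Nfkbiz itself was far higher in the Nfkbiz group on 1 of its 3 probe sets. Probe set 1448728_a_at rose from an intensity of 210.2 ± 26.7 to 3501 ± 1307 (SD, n = 3 per group), a 15.8-fold difference (log2 difference 3.98 ± 0.27 SE, limma adjusted p = 0.0009 over 27022 probe sets), and it had the smallest p of all probe sets. The luciferase arrays read 221, 230 and 180 there and the Nfkbiz arrays 4424, 4073 and 2006. The brightest probe set of the gene, 1417483_at, read 836 ± 121 against 1042 ± 241 (log2 difference 0.30 ± 0.19, limma adjusted p = 0.603 over the probe sets). It represented Nfkbiz in the gene-level fit, where its limma adjusted p was 0.554. The dimmest, 1457404_at, read 111 ± 49.8 against 64.8 ± 34.3 (-0.89 ± 0.54, limma adjusted p = 0.594 over the probe sets). Neither passed the threshold. Which part of the transcript each probe set reads, and which part the vector carried, are not given in the sources used here.

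**Figure D1:**
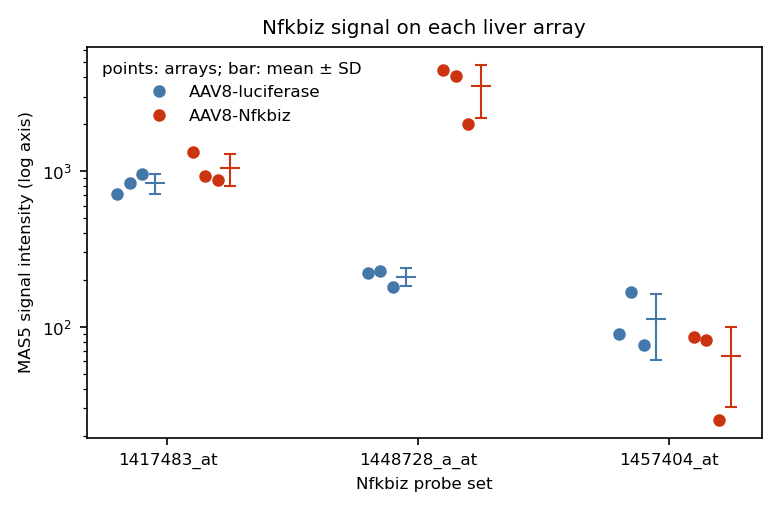
MAS5 intensity of the 3 Nfkbiz probe sets (log axis) on each array of the AAV8-luciferase and AAV8-Nfkbiz groups, with the mean ± SD of each group beside the points. On 1448728_a_at the Nfkbiz arrays lie between 2006 and 4424 and the luciferase arrays between 180 and 230, while the groups overlap on 1417483_at and on 1457404_at.

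Across the liver transcriptome 30 of 13312 genes passed the threshold, 9 higher and 21 lower in the Nfkbiz livers, and the arrays of the groups did not overlap for any of the 30. The largest falls were in the lipin gene Lpin1, a phosphatidate phosphatase of glycerolipid synthesis, in the lysophosphatidylcholine transporter Mfsd2a, in Zbtb16, and in the clock-controlled Usp2. The largest rises past the threshold among named genes were in the granzyme gene Gzma, in Socs2, a feedback inhibitor of growth hormone signalling, and in Cda, the cytidine deaminase gene. Lpin1 dropped from 4729 ± 1870 to 787 ± 155 (SD, n = 3), a log2 difference of -2.53 ± 0.26 (SE, limma adjusted p = 0.0035), and Mfsd2a from 6728 ± 639 to 1723 ± 663 (-2.03 ± 0.23, limma adjusted p = 0.00706). Zbtb16 changed by -2.02 ± 0.19 and Usp2 by -1.85 ± 0.16, with limma adjusted p-values of 0.00285 and 0.00276. Socs2 rose from 741 ± 103 to 2189 ± 218 (1.57 ± 0.15, limma adjusted p = 0.00285), and Cda from 640.1 ± 77.6 to 1699 ± 35.5 (1.42 ± 0.14, limma adjusted p = 0.0032).

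The other genes that fell included transcriptional regulators and metabolic genes. Tsc22d3, a glucocorticoid-induced leucine zipper gene, fell by 1.61 ± 0.23 on the log2 scale, the forkhead factor gene Foxo3 fell by 1.53 ± 0.21, and Klf15, a regulator of amino acid and glucose metabolism, fell by 1.45 ± 0.21. Herpud1, a component of ER-associated degradation, fell by 1.45 ± 0.23, the clock gene Per1 by 1.36 ± 0.20, the fatty acid synthase gene Fasn by 1.33 ± 0.21, the lipin gene Lpin2 by 1.25 ± 0.15 and the coactivator gene Ppargc1a by 1.24 ± 0.20, with limma adjusted p-values from 0.0141 for Lpin2 to 0.0449 for Ppargc1a. Among the genes that rose, Gzma changed by 1.77 ± 0.28, Ctla2b by 1.29 ± 0.20, Wfdc17 by 1.22 ± 0.13, the interferon-inducible GTPase gene Ifi47 by 0.86 ± 0.12, Id2 by 0.81 ± 0.13 and the homeobox gene Hhex by 0.81 ± 0.13, with limma adjusted p-values from 0.00468 for Wfdc17 to 0.0427 for Gzma. Another probe set of Id2 went the other way, at -0.91 ± 0.36. Hsd3b5 had the largest positive difference of the named genes, 2.65 ± 0.47, without passing the threshold (limma adjusted p = 0.0625), and neither did Mmrn2 (1.04 ± 0.18), Adgre4 (1.07 ± 0.21) or the cold-inducible Cirbp (1.01 ± 0.20), with limma adjusted p-values of 0.0563, 0.101 and 0.105.

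At an unadjusted p below 0.05, 1601 genes were found, 669 higher and 932 lower, where 665.6 were expected by chance, and the groups did not overlap for 18.0% of genes, where chance gives 10%. With limma's variance prior without the intensity trend, 0 genes passed (1350 at an unadjusted p below 0.05). Leaving out any 1 array gave between 8 and 19 genes, of which between 8 and 13 were among the 30. Cda, Lpin1, Socs2, Usp2, Wfdc17 and Zbtb16 passed in every case, and Gzma, Id2, Hhex and Ppargc1a in none. The gene lists below were called with a preset correlation between members, and with an estimated correlation 0 of the 29 lists passed after adjustment and 3 passed unadjusted (clock, lipogenesis and interferon response), while fry called the clock list. Among the 9 lists called, other splits of the arrays gave as small a camera p for chemokines, male-biased genes, T and NK cell markers and gluconeogenesis. These splits of the 6 arrays into 3 and 3 called up to 17 lists against 9 for the real groups, and up to 1 gene against 30. At an unadjusted p below 0.05 they gave between 257 and 998 genes against 1601.

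Genes of de novo lipogenesis, the synthesis of fatty acids from acetyl-CoA, were lower in the Nfkbiz livers. Of 20 measured members, 1 fell over all genes, Fasn, and 8 fell and 0 rose when adjusted over the list alone: Fasn, Thrsp (-1.47 ± 0.31), Acaca (-0.87 ± 0.21), Elovl6 (-0.82 ± 0.18), the lipogenic regulators Srebf1 (-0.65 ± 0.16) and Mlxipl (-0.58 ± 0.20), Acly (-0.46 ± 0.15) and Gpam (-0.40 ± 0.12). A second Acaca probe set read 0.34 ± 0.43. The list had a median log2 difference of -0.23 and was shifted downward (camera adjusted p = 0.00031, and adjusted p = 0.308 with an estimated correlation). Its median was -0.36 without the third Nfkbiz array. Scd1, at 10212 ± 5116 against 6954 ± 1830 (SD, n = 3), did not pass in either count (-0.45 ± 0.35), and Pnpla3 had a positive difference of 1.56 ± 0.82.

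Within triglyceride synthesis and lipid droplet genes, the 2 lipins fell and the rest did not pass. Of 25 measured members, Lpin1 and Lpin2 were the 2 that fell over all genes and also when adjusted over the list alone, and the list as a whole was not shifted (median -0.08, camera adjusted p = 0.607). That median ran from -0.15 without the first to 0.08 without the second luciferase array, and was 0.05 with the mean of probe sets and 0.08 with the most variable probe set. The lipid droplet coat gene Plin2 read 15467 ± 1020 against 20588 ± 2798 (0.41 ± 0.13), and the fatty acid transporter gene Cd36 6127 ± 1508 against 6583 ± 1143 (0.12 ± 0.20), and neither passed. The other probe sets of Cd36 had differences of -0.03 and -0.21. Among 27 genes of fatty acid oxidation and PPARα targets, Ppargc1a was the 1 that fell over all genes and when adjusted over the list alone (median 0.11, camera adjusted p = 0.303, passing at 0.12 without the third Nfkbiz array and not at 0.02 without the second). That median was 0.02 after quantile and 0.00077 after loess normalization. Acot1 (1.18 ± 0.34), Pdk4 (0.73 ± 0.22), Ppara (-0.38 ± 0.15) and Cpt1a (-0.06 ± 0.15) did not pass. Both the triglyceride and the oxidation list passed fry's test for changes in either direction (fry adjusted p = 0.0091 for each).

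Circadian clock genes were mostly lower in the Nfkbiz livers. Of 15 measured members, Usp2 and Per1 fell over all genes, and 8 fell and 1 rose when adjusted over the list alone. Those that fell were Ciart (-3.22 ± 0.55), Usp2, Dbp (-1.54 ± 0.36), Per1, Per2 (-0.92 ± 0.19), Per3 (-0.84 ± 0.22), Tef (-0.61 ± 0.14) and Nr1d2 (-0.55 ± 0.15), most of them genes under control of the CLOCK-BMAL1 activator, and Clock rose (0.65 ± 0.22). Arntl, the gene of BMAL1, had a difference of 0.61 ± 0.40 and did not pass. The list was shifted downward, with a median of -0.56 (camera adjusted p = 2.2e-05, fry adjusted p = 0.0076, and adjusted p = 0.22 with an estimated correlation). Ciart read 228, 441 and 442 on the luciferase arrays and 66.2, 14.4 and 57.2 on the Nfkbiz arrays, its limma adjusted p over all genes being 0.0587.

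**Figure D2:**
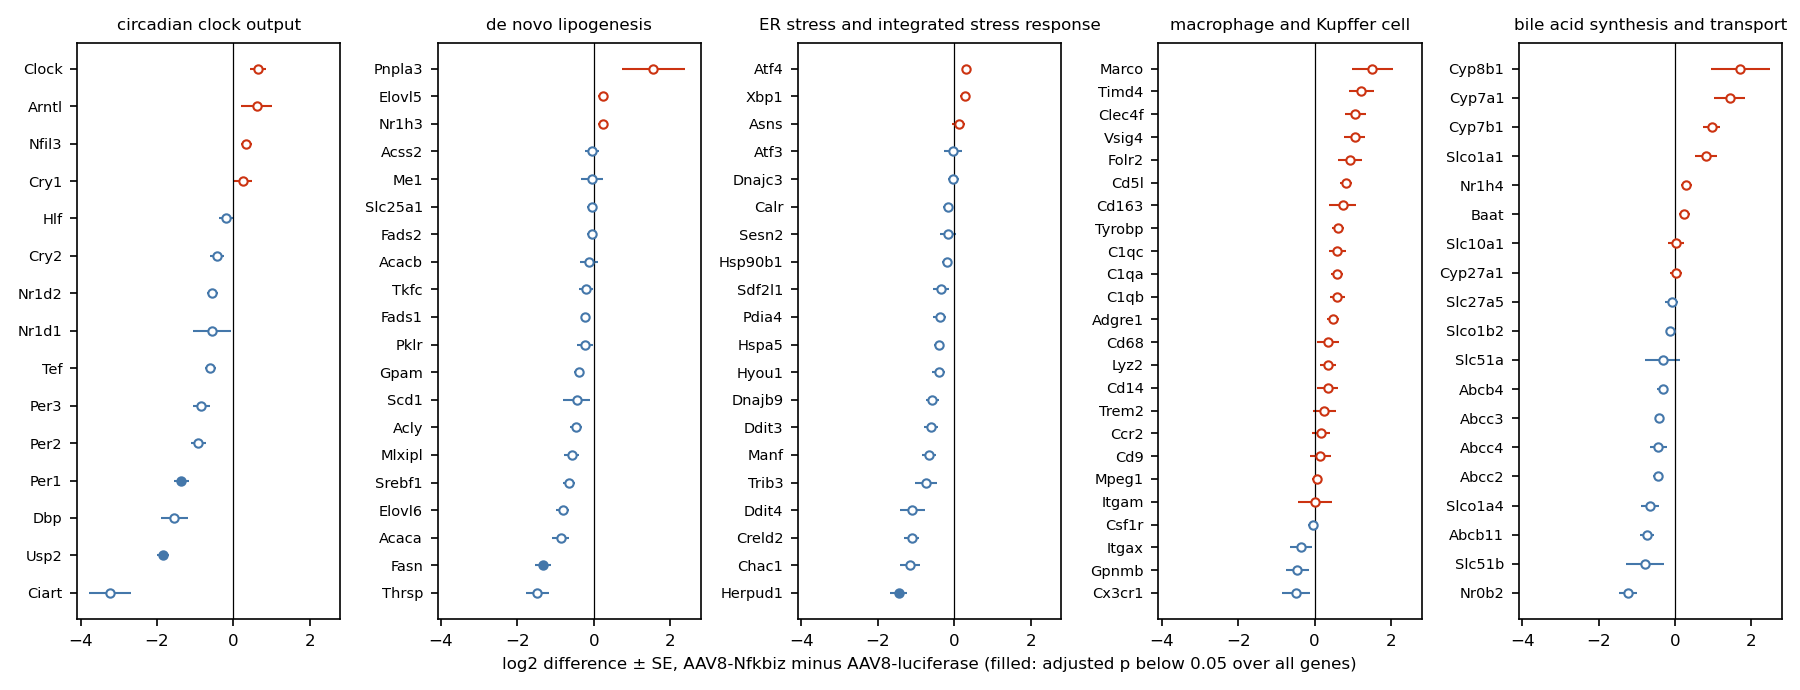
Log2 differences (AAV8-Nfkbiz minus AAV8-luciferase, points, with SE as bars) of the measured members of 5 gene lists: circadian clock, de novo lipogenesis, ER stress, macrophage and Kupffer cell, and bile acid genes. Filled points passed the threshold over all genes (Per1, Usp2, Fasn and Herpud1). Ciart lies lowest, at -3.22, and the bile acid panel holds differences from -1.24 (Nr0b2) to 1.71 (Cyp8b1).

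Genes of ER stress and the integrated stress response were also lower. Herpud1, read at 13836 ± 2758 in the luciferase and 5146 ± 1473 in the Nfkbiz group (SD, n = 3), was the 1 of 20 members that fell over all genes. When adjusted over the list alone 8 fell and 1 rose. The 8 were Herpud1, Chac1 (-1.16 ± 0.26), Creld2 (-1.11 ± 0.19), Ddit4 (-1.10 ± 0.32), Manf (-0.66 ± 0.18), Ddit3 (-0.60 ± 0.18), Dnajb9 (-0.58 ± 0.17) and the chaperone gene Hspa5 (-0.40 ± 0.13), and Atf4 rose (0.31 ± 0.11). The list had a median of -0.39 and was shifted downward (camera adjusted p = 2.2e-05, and adjusted p = 0.436 with an estimated correlation). Its median was -0.25 without the first luciferase array.

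Macrophage and Kupffer cell markers were higher in the Nfkbiz livers. None of the 24 measured markers passed limma's test over all genes, and 11 rose and 0 fell when adjusted over the list alone. They included markers of resident Kupffer cells, Marco (1.5 ± 0.54), Timd4 (1.22 ± 0.32), Clec4f (1.07 ± 0.28), Vsig4 (1.05 ± 0.27), Folr2 (0.93 ± 0.31) and Cd5l (0.83 ± 0.16), the complement genes C1qa, C1qb and C1qc (0.59 each), Tyrobp and Adgre1, the F4/80 gene (0.47 ± 0.15). The list's median was 0.42 (camera adjusted p = 2.7e-06, and adjusted p = 0.436 with an estimated correlation). Without the third luciferase array, which stood apart on the second principal component, it was 0.24 and the list still passed. Trem2, Gpnmb, Itgax, Cx3cr1, Cd9 and Ccr2, which mark recruited or lipid-associated macrophages, lay between -0.48 and 0.26 and did not pass.

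Interferon response genes were shifted upward together. Of 20 measured members 0 passed limma's test over all genes, and 8 rose and 0 fell when adjusted over the list alone: Cxcl9 (0.87 ± 0.27), Gbp2 (0.86 ± 0.23), Zbp1 (0.65 ± 0.21), Ifit2 (0.60 ± 0.18), Oas1a (0.57 ± 0.19), Irf7 (0.52 ± 0.14), Rtp4 (0.50 ± 0.12) and Gbp3 (0.45 ± 0.16), with a median of 0.32 (camera adjusted p = 2.9e-06, and adjusted p = 0.393 with an estimated correlation). That median was 0.21 without the first and 0.50 without the third luciferase array, and the list passed in both cases. Chemokine and cytokine genes, which share Cxcl9 and Cxcl10 with that list, had a median of 0.35 (camera adjusted p = 0.00031, and adjusted p = 0.529 with an estimated correlation), and 0 of 20 passed over all genes or when adjusted over the list alone, Ccl7 (1.11 ± 0.52), Il1b (0.82 ± 0.33) and Ccl5 (0.66 ± 0.26) among them. Their median was 0.22 without the first and 0.53 without the second Nfkbiz array, with the call kept. T and NK cell markers had a median of 0.46 (camera adjusted p = 0.0099, and adjusted p = 0.658 with an estimated correlation), with Gzma the 1 of 15 that rose over all genes and when adjusted over the list alone. Without the first Nfkbiz array that median was 0.12 and the call was lost, and without the second it was 0.74. Neutrophil markers (median 0.26, 0 of 10 passing in either count, camera adjusted p = 0.101) and B and plasma cell markers (0.25, 0 of 10 in either count, camera adjusted p = 0.0623) did not pass with all arrays. With an estimated correlation the camera adjusted p was 0.673 for both lists. For each, 3 of the 10 splits of the arrays, the real one included, gave as small a camera p. The neutrophil list passed without the second (median 0.35) or the third Nfkbiz array (0.31) and without the filter (0.30). Its median was 0.09 without the third luciferase array. The B cell list passed without the first luciferase array (0.43) or the second (0.40) or the third Nfkbiz array (0.43). Its median was 0.12 without the first Nfkbiz array. It also passed after median centring (0.29) or loess normalization (0.28), without the variance trend (0.25), with array weights (0.32) and with the mean of probe sets (0.41).

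Genes reported elsewhere as IκBζ targets, mostly from macrophages and epithelia, did not pass as a list. Of 12 measured, 9 had a positive difference and 0 passed over all genes or when adjusted over the list alone (median 0.35, camera adjusted p = 0.0623). With an estimated correlation the camera adjusted p was 0.755. As small a camera p came from 5 of the 10 splits of the arrays, the real one included. The list passed without the first luciferase array (median 0.45) and without the second (0.54) or the third Nfkbiz array (0.45). It had a median of 0.22 without the third luciferase array and 0.11 without the first Nfkbiz array. S100a9 (0.84 ± 0.35) and S100a8 (0.85 ± 0.36) had the smallest p-values among them, and Lcn2 read 16192 ± 2721 against 16252 ± 3980 (SD, n = 3), with a log2 difference of -0.01 ± 0.20, whose sign is opposite to that of the intensity means. NF-κB feedback and target genes had a median of 0.08 with 0 of 18 passing in either count (camera adjusted p = 0.393). Leaving out 1 array moved that median between 0.05 (the first Nfkbiz array) and 0.21 (the first luciferase array), and it was -0.0041 with the mean of probe sets. Nfkbia, the IκBα gene, had a difference of -0.42 ± 0.15. Acute phase genes had a median of 0.11 with 0 of 24 passing in either count (camera adjusted p = 0.0647), Saa1 at 20481 ± 3523 against 26431 ± 7368 (0.35 ± 0.20) and Apcs at 0.48 ± 0.15. The acute phase list had a camera adjusted p of 0.807 with an estimated correlation. As small a camera p came from 7 of the 10 splits. That list passed without the second (median 0.20) or the third luciferase array (0.12) and without the second (0.12) or the third Nfkbiz array (0.18). Its median was 0.04 without the first luciferase array and -0.00074 without the first Nfkbiz array, 0.03 after quantile and 0.00093 after loess normalization. Ccl2 had a difference of 0.31 ± 0.32, and Il6 and Tnf were below the intensity filter, with group means of 15.0 and 27.9 for Il6 and 20.2 and 17.3 for Tnf.

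Fibrosis and stellate cell genes had mostly negative differences, 21 of 27, and 0 passed over all genes or when adjusted over the list alone (median -0.15, camera adjusted p = 0.0637). Col1a1 read 397.3 ± 99.2 against 265.5 ± 26.1 (-0.56 ± 0.21), Ccn2 had a difference of -1.04 ± 0.30, Acta2 of -0.15 ± 0.21, Timp1 of 0.05 ± 0.40 and the collagenase gene Mmp13 of 1.02 ± 0.26. The call turned on single arrays and on the processing. Without the third luciferase array the median was -0.47 and the list passed, as it did without the third Nfkbiz array (-0.31), and without the first luciferase array it was 0.01. With all arrays the list passed after quantile, median or loess normalization and without the filter, among other settings given below. Its camera adjusted p was 0.807 with an estimated correlation. As small a camera p came from 8 of the 10 splits of the arrays, the real one included. Cholangiocyte markers had a median of -0.62 with 0 of 8 passing in either count (camera adjusted p = 0.0623), Epcam at -0.64 ± 0.25 and Krt19 at -0.92 ± 0.50. Their camera adjusted p was 0.755 with an estimated correlation, and 5 of the 10 splits gave as small a camera p. Without the first luciferase array their median was -0.16. They passed without the second (-0.73) or the third luciferase array (-0.86), without the third Nfkbiz array (-0.67), after quantile (-0.58), median (-0.59) or loess normalization (-0.56), with array weights (-0.61) and on ranks. Sinusoidal endothelial markers went both ways, Clec4g at 0.63 ± 0.21 and Vwf at -1.10 ± 0.34, with 0 of 15 passing in either count (median 0.19, camera adjusted p = 0.403). Their median changed sign without the third luciferase array (-0.25) and with array weights (-0.12), while they passed without the second luciferase array (0.46).

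Bile acid genes split into those with higher and those with lower expression. Of 19 members 0 passed limma's test over all genes, and 3 rose and 5 fell when adjusted over the list alone. Cyp7a1, the rate-limiting enzyme of the classic bile acid pathway, rose from 3688 ± 2677 to 8278 ± 214 (1.43 ± 0.40), with Cyp7b1 of the alternative pathway (0.96 ± 0.22) and the transporter gene Slco1a1 (0.80 ± 0.29). Nr0b2, the gene of the repressor SHP (-1.24 ± 0.24), the bile salt export pump gene Abcb11 (-0.74 ± 0.18), Slco1a4 (-0.66 ± 0.24), Abcc2 (-0.44 ± 0.13) and Abcc3 (-0.41 ± 0.12) fell. With members going both ways the list was not shifted (median -0.12, camera adjusted p = 0.403), and fry's test for changes in either direction gave an adjusted p of 0.045. That median was -0.20 without the first luciferase array, -0.24 after quantile normalization, -0.22 after loess normalization, and -0.32 with the mean of probe sets or the most variable probe set. Cyp8b1 had a difference of 1.71 ± 0.78 and did not pass. Passing fry's test for changes in either direction was not particular to bile acid genes. It passed 6 of the 29 lists, the others being lipogenesis, triglyceride synthesis, fatty acid oxidation, ER stress and the clock.

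Male-biased liver genes, which include Cyp7b1 and Slco1a1 of the bile acid list, were shifted upward. None of the 11 measured passed limma's test over all genes, and 3 rose and 0 fell when adjusted over the list alone: Hsd3b5, at 52.9 ± 11.7 against 379 ± 225 (SD, n = 3), Cyp7b1 and Serpina12 (0.86 ± 0.25). The median was 0.42 (camera adjusted p = 5e-05, and adjusted p = 0.436 with an estimated correlation). Female-biased genes went both ways, with 0 of 7 passing over all genes and 1, Acot3 (1.12 ± 0.32), rising when adjusted over the list alone. Their median was -0.64, their mean -0.17, and the list was not shifted (camera adjusted p = 0.717), its median being 0.22 without the filter. Leaving out 1 array moved it between -0.77 (the first luciferase array) and -0.07 (the third Nfkbiz array). Of the Y-linked genes, Eif2s3y read between 1599 and 1848 over the arrays of both groups, Kdm5d between 321 and 542 and Uty between 301 and 575. Xist read between 57.2 and 156. These values argue against a difference in sex between the groups.

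Genes of gluconeogenesis and glucose metabolism had a median of -0.22 and lay at the edge of the threshold (camera adjusted p = 0.0486, and adjusted p = 0.529 with an estimated correlation). Of 13 members 0 passed limma's test over all genes and 1, Foxo1 (-0.71 ± 0.18), fell when adjusted over the list alone, and Pck1 had a difference of -0.47 ± 0.15. Leaving out the second luciferase array ended the call (median -0.18), as did leaving out the second (-0.21) or the third Nfkbiz array (-0.26). With all arrays it also ended with median centring (-0.19), the strict filter (-0.22), no variance trend (-0.22), the mean of probe sets (-0.16), the most variable probe set (-0.13), the replicate number as a block (-0.22) and fry. Cytochrome P450 and drug metabolism genes had a median of 0.01 and a mean of -0.05 with a test directed downward (camera adjusted p = 0.403). Of 17, 0 passed over all genes and 3 fell when adjusted over the list alone: Nr1i2, the gene of the xenobiotic receptor PXR (-0.65 ± 0.17), Fmo5 (-0.54 ± 0.15) and Cyp1a2 (-0.53 ± 0.12). The list passed after quantile (median -0.09) or loess normalization (-0.10), without the first luciferase array (-0.11) and without the second Nfkbiz array (-0.15). Its median was 0.10 without the second luciferase array.

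Camera did not call the other hepatocyte programmes with all arrays and the authors' scaling. Of 16 hepatocyte identity genes, Tat, the tyrosine aminotransferase gene, was the 1 that fell over all genes and when adjusted over the list alone (-1.17 ± 0.16, limma adjusted p = 0.0218). That list had a median of 0.03, a mean of -0.16 and a test directed downward (camera adjusted p = 0.403), and it passed after quantile (median -0.04) or loess normalization (-0.09) and without the first luciferase array (-0.05). That median was 0.10 without the third Nfkbiz array. Cholesterol synthesis genes had a median of 0.03 (camera adjusted p = 0.763), with 0 of 20 passing over all genes and 1, Srebf2 (-0.62 ± 0.15), falling when adjusted over the list alone. Their list passed in opposite directions without the first (median 0.21) and without the second Nfkbiz array (-0.17). Genes of lipoprotein assembly and secretion (median 0.04, 0 of 15 passing in either count, camera adjusted p = 0.403) and of phosphatidylcholine and methyl metabolism (0.04, 0 of 16 in either count, camera adjusted p = 0.685) did not pass, and both medians were at or below 0 after quantile or loess normalization. Leaving out 1 array moved the lipoprotein median between -0.01 (the first luciferase array) and 0.09 (the third Nfkbiz array), and the phosphatidylcholine median between -0.08 and 0.11 (the first and the second luciferase array). Mttp, which loads lipid onto apolipoprotein B, read 4584 ± 228 against 4666 ± 230 (0.03 ± 0.11), and Chka had a difference of 0.58 ± 0.18, with its other probe sets at -0.02 and -0.47.

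Among stress and growth lists, NRF2 and oxidative stress genes had a median of -0.10 with 0 of 17 passing in either count (camera adjusted p = 0.474), Hmox1 at 0.42 ± 0.16 and Pgd at -0.42 ± 0.14. Their median lay between -0.22 (without the second Nfkbiz array) and -0.02 (without the first luciferase array) when 1 array was left out. The 2 probe sets of Mt1 disagreed, at 0.91 ± 0.29 and -2.21 ± 0.95. Cell cycle genes had a median of 0.15 with 0 of 21 passing in either count (camera adjusted p = 0.403), Ccnb2 at 0.69 ± 0.36 and Foxm1 at -1.32 ± 0.40, and passed without the first Nfkbiz array (median 0.48). Their median was -0.03 without the second luciferase array. Apoptosis and p53 genes had a median of 0.07 and a mean of -0.0035 (camera adjusted p = 0.735), with 0 of 14 passing over all genes and 1, Trp53inp1 (-0.78 ± 0.17), falling when adjusted over the list alone. Without the first Nfkbiz array their median was 0.15, and without the third it was -0.12. Erythrocyte markers and markers of neighbouring fat and pancreas had 4 measured members each and were not tested as lists. Their medians were 0.06 and 0.26, and 0 members of either passed limma's test in either count.

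**Figure D3:**
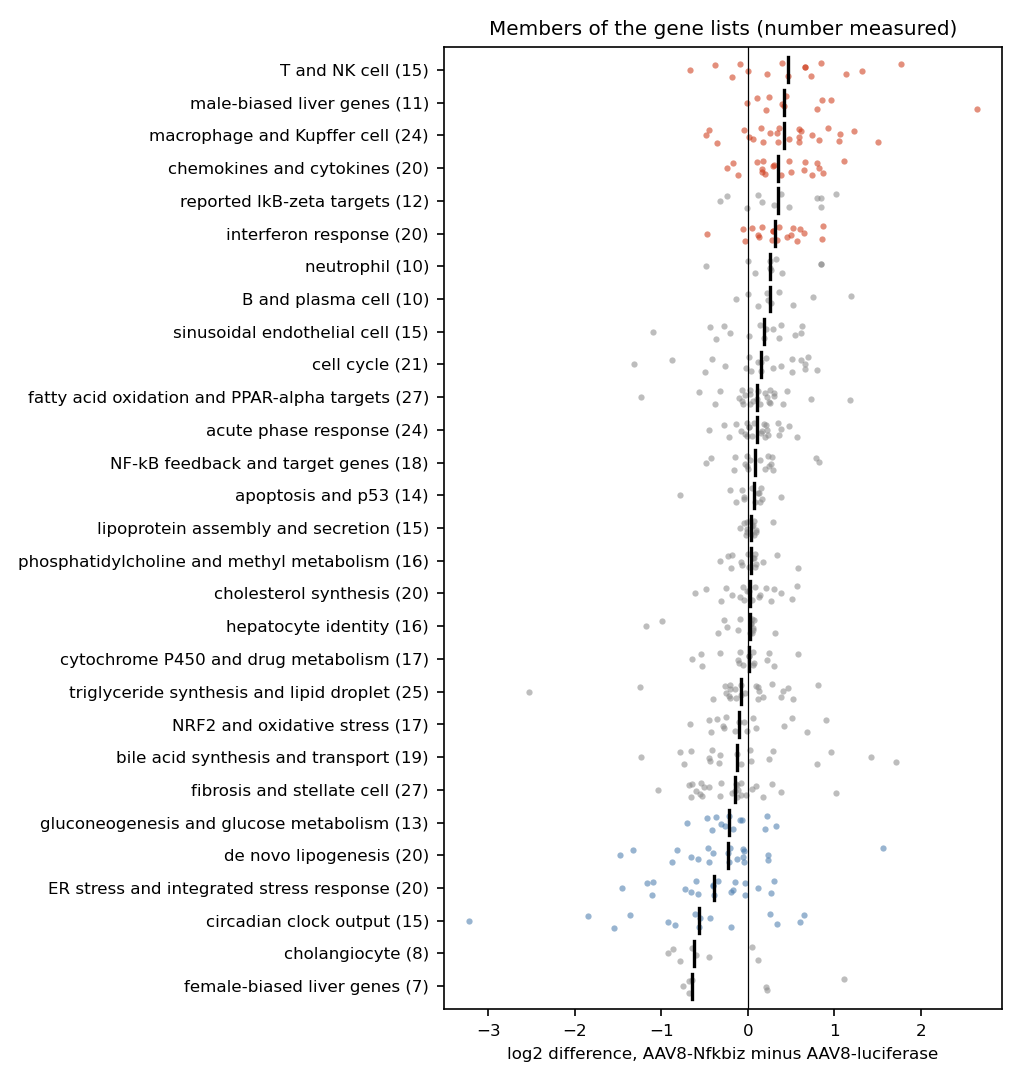
Log2 differences (AAV8-Nfkbiz minus AAV8-luciferase) of the measured members of the 29 tested gene lists, 1 point per gene, with the median of each list as a black bar and the number of measured members in brackets. Red lists were shifted upward and blue lists downward by camera with a preset correlation, and grey lists did not pass. The medians of the 9 coloured lists run from -0.56 (circadian clock) to 0.46 (T and NK cell markers).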

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

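The tests on the Nfkbiz probe sets were chosen after the result was seen. The signal stood out because it came from a probe set that the gene-level comparison did not use: Nfkbiz was represented there by its brightest probe set, 1417483_at, which did not pass, while 1448728_a_at was 15.8-fold higher in the Nfkbiz livers than in the luciferase livers. A swap of arrays between the groups is argued against by that probe set, since the lowest Nfkbiz array read 8.74-fold above the highest luciferase array. A candidate explanation for the silence of the other probe sets is that the vector's transcript lacks the parts they read. The difference of 0.30 on the brightest other probe set leaves this open, because the positions of the probes and of the insert are not given in the sources used here.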

How the results depend on the processing

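All alternatives here were planned before the data were examined. Directions held widely while thresholds did not. Of the 21 named genes past the threshold, 201 of 271 comparisons with all arrays kept direction and call, 69 lost the call and 1 reversed (Id2, -0.91 with the most variable probe set, another probe set by construction). Leaving out 1 array kept 57 of 126 and lost 69. A reversal could not occur there, since the groups did not overlap for any gene past the threshold. Of 124 named genes that did not pass, 24 of 2324 comparisons passed and 37 changed sign. For the 22 other tested lists, 426 of 481 comparisons stayed on their side, 25 lost the call, 29 gained it, 27 changed the direction of the test without a call and 1 reversed (cholesterol synthesis, -0.17 without the second Nfkbiz array against 0.21 without the first, the cause was not tested). For the 7 primary lists, 128 of 154 stayed, 2 lost the call, 24 gained it and 4 changed the direction of the test without a call. Median, quantile or loess normalization moved the median of all genes by at most 0.03, and precision was limited by 3 arrays per group, with dim genes left out by the filter.

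The counts of 9 genes higher and 21 lower became 0 and 0 with limma without the trend (1350 at an unadjusted p below 0.05) and with a Welch test per gene (1018 unadjusted). They were 22 and 40 with array weights, 4 and 9 with the mean of probe sets, 4 and 6 with the most variable probe set, and 5 and 14 with probe sets as the unit. An unadjusted p with a log2 difference of at least 1 gave 78 and 98, a looser threshold by construction. Leaving out 1 array gave 4 to 8 higher and 3 to 11 lower, with 14, 8 and 19 genes in all without luciferase arrays 1, 2 and 3 and 9, 16 and 14 without Nfkbiz arrays 1, 2 and 3, from fewer samples. The Nfkbiz probe set, at 3.98, lost its call without the trend (adjusted p 6.1e-05 to 0.087 over the alternatives), and the gene passed at 3.98 with the most variable probe set, which is that probe set. The 9 lists shifted became 14 with loess normalization, 14 with array weights, 0 with an estimated correlation (3 unadjusted), 1 with fry, and 10 to 15 leaving out 1 array (14 without the second and 15 without the third Nfkbiz array). Lipogenesis, at -0.23, lost its call with an estimated correlation and with fry, which change the test and not the median. Apart from the choices of probe sets, the threshold and the set tests, the cause was not tested.

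The fibrosis list passed at -0.16 with quantile, -0.11 with median and -0.16 with loess normalization, -0.17 without the filter, -0.24 with array weights, -0.28 with the mean of probe sets, -0.16 with the most variable probe set and -0.15 on ranks, and ran from -0.47 to 0.0097 leaving out 1 array. The IκBζ target list passed at 0.38 with median centring, 0.45 with array weights, 0.35 with the replicate block and 0.35 on ranks, and ran from 0.11 to 0.54 leaving out 1 array. The acute phase list passed at 0.13 with array weights and 0.11 with the most variable probe set, was at 0.03 with quantile and 0.00093 with loess normalization, and ran from -0.00074 to 0.20 leaving out 1 array. Fatty acid oxidation was at 0.02 with quantile and 0.00077 with loess normalization, and ran from 0.015 to 0.12 leaving out 1 array, passing without the third Nfkbiz array. The cause was not tested for these lists. Replicate numbers did not pair the samples: same-number correlations were -0.06, 0.07 and -0.03. With them as a block, 27 genes passed, 21 of them shared with the 30.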

Other observations

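The tests on heat shock, glucocorticoid-induced, clock-phase and Kupffer subset genes were chosen after the results were seen, whereas the counts over other splits were planned. Heat shock genes, which encode chaperones of the protein folding response to heat, had mostly negative differences in the Nfkbiz livers, 14 of 16 measured (13 after median centring), with a median of -0.35. Hsph1 fell over all genes (-1.05 ± 0.15, limma adjusted p = 0.0316), a call lost when any 1 array was left out, while Hspa1b (-1.03 ± 0.19), Hspa1a (-0.69), Dnajb1 (-0.66), Hspa8 (-0.64) and Bag3 (-0.62) did not pass singly and Hspe1 had a difference of 0.37. The cold-inducible Cirbp had a difference of 1.01 ± 0.20. A lower body temperature at sampling was considered after Cirbp, Hsph1 and other heat shock genes had been seen. Over the 9 members whose values had not been seen, the median was -0.16, 7 of them negative (camera p = 0.0189, and p = 0.0713 with an estimated correlation), so this stays open.

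Lower glucocorticoid signalling in the Nfkbiz livers was considered and stays open, since its test was void. The set of 20 genes known to be induced by glucocorticoids was put together after Lpin1 (-2.53), Zbtb16 (-2.02), Tsc22d3 (-1.61), Per1 (-1.36) and Tat (-1.17) had been seen to fall, and it is incomplete, since Klf15, which also fell, is not in it. The median of -0.25 over the 15 members that did not pass, 10 negative and 5 positive, decides nothing, because the threshold itself sorted the members. Among them were Ddit4 (-1.10), Klf9 (-0.85 ± 0.14), Errfi1 (-0.81 ± 0.14), Gadd45b (0.58) and Mt1 (0.91).

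The clock pattern was that evening-phase genes (10 of 10 lower, median -0.88) and morning-phase genes (4 of 4 higher, median 0.47, camera p = 0.0678 with an estimated correlation, none passing over all genes) differed by -1.35. The evening minus morning score ran from 0.83 to 1.39 on the luciferase arrays and from -1.08 to -0.12 on the Nfkbiz arrays (exact two-sided permutation p = 0.1, the smallest possible). Both sets were drawn from the clock list after its values had been seen, and the 4 morning-phase genes were its 4 members with a positive difference. These counts and p-values therefore describe the pattern and do not test it. A factor that scales a whole array shifts both gene sets alike and drops out of the gap by construction. The gap of -1.35 after quantile normalization is therefore no test of such scaling. A different clock phase or sampling time stays open, since the gap of -1.35 is the pattern itself and lends it no support. An effect of the vector on the clock stays open as well: the Nfkbiz array with the least Nfkbiz signal scored 0.51 above the mean of the others, which decides nothing with 3 arrays. Sampling times are not given, so time and vector may be confounded, for the clock score and for every other difference between the groups.

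The Kupffer pattern was that 7 resident Kupffer cell markers had a median of 1.05 and 6 recruited macrophage markers one of -0.10, sets drawn after the macrophage list had been seen, so these medians describe the pattern and do not test it. A lower share of hepatocytes could raise the markers of every other cell type alike, yet cholangiocyte (-0.51 ± 0.56) and stellate markers (-0.22 ± 0.32) did not go up with the macrophage markers (0.44 ± 0.18). Macrophage minus cholangiocyte markers differed by 0.949 ± 0.535 (exact p = 0.3), and macrophage minus stellate markers, a contrast added after that first one had left the question undecided, by 0.655 ± 0.266 (exact p = 0.1), so the share of hepatocytes stays open. A change in resident Kupffer cells rather than recruited macrophages is open too, the resident minus recruited contrast of 1.17 ± 0.713 (exact p = 0.2) being taken on those same sets. Its bound was first an overlap of the groups, which was met, with luciferase array 2 at 1.31 above Nfkbiz array 3 at 1.17, and was changed because 1 overlapping array of 3 does not forbid a rise.

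With 10 splits of the 6 arrays into 3 and 3, a share under 0.05 cannot be reached. For genes, 1 of the 10 splits, the real one, called 30 or more, and the highest other called 1. For gene lists, 8 of the 10 splits called 9 or more, the real groups calling 9 and the highest other split 17. For the lists of the clock, ER stress, macrophages, interferon response and lipogenesis, no other split gave as small a camera p. With 10 splits this happens by chance for 1 list in 10, and 29 lists were tested. In this permutation of the group labels, macrophages had 9.3e-08 with the real groups and 3.5e-07 with the nearest other split. The permutation gave 2.0e-07 and 7.0e-07 for the interferon response, so both margins were narrow. It gave 7.5e-05 and 0.00049 for lipogenesis, 2.3e-06 and 0.00013 for ER stress, and 3.1e-06 and 0.014 for the clock. For the other called lists, splits with a p as small, the real one included, numbered 4 of 10 for chemokines and cytokines, 3 for male-biased genes, 3 for T and NK cell markers and 2 for gluconeogenesis.

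A probe set with no gene in the annotation used, 1442025_a_at, had the same adjusted p as the Nfkbiz probe set, at 1184 ± 390.5 in the luciferase and 109 ± 17.1 in the Nfkbiz livers (SD, n = 3), a log2 difference of -3.40 ± 0.24 (limma adjusted p = 0.0009).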
